A study of Mus musculus with 15 samples.

How the data were processed

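Small RNA was sequenced from mouse Kupffer cells, the resident macrophages of the liver, of C57BL/6J mice (wt) and of ob/ob mice, which lack functional leptin and become obese. The 15 libraries fall into wt at 9 weeks (n = 4), ob/ob at 9 weeks (n = 3), wt at 14 weeks (n = 4) and ob/ob at 14 weeks (n = 4). Per the labels' protocols, small RNA was isolated with a column kit, libraries were made with the TruSeq Small RNA kit and sequencing was done on an Illumina HiSeq. The submitters' processing notes name bcl2fastq, cutadapt and the builds GRCm38.p5 and mm10. The aligner, the counting tool and the miRNA annotation are not given in the sources used here. The lane numbers in the labels put all libraries of 9 weeks in lane 2. At 14 weeks, replicates 1 and 2 of both genotypes were in lane 1 and replicates 3 and 4 in lane 2.

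The deposited values were taken as RPM (reads per 1000000 reads) made by the authors, 1 table per age, with the same 248 mature miRNAs in both. The unit is not stated and was inferred from the values. Low values in each library were whole multiples of 1 step within 0.1 reads, read as the worth of 1 read. The values of 24 to 71 miRNAs per library were low enough for this, with 100.0% of them whole. Higher values did not allow the same check, so whole reads were not recovered and no count model was used. Which reads form the denominator is not given in the sources used here. The step implies a depth of 9.08 to 98.0 M reads (M, 1000000) per library, and 1 RPM stands for 9.08 to 98.0 reads. These reads are not independent molecules. The depth is given here to gauge counting error, which does not exclude that RPM values shift with depth.

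Some miRNAs are listed at exactly 0 in single libraries beside high values in others, miR-126a-3p and miR-93-5p among them, while miR-151-3p is high in 1 library of each age and at 0 to 4.40 RPM in the rest. An exact 0 may therefore be a failed assignment. Values of miRNAs made from more than 1 locus, 22 of the 248, depend on how shared reads were assigned, which is not given in the sources used here. The same holds for close relatives such as the let-7 family.

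The design fixed before the data were examined foresaw a count test, or limma-trend should the tables hold normalized values. The latter applied. log2(RPM + 0.5) was tested with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, Benjamini-Hochberg adjustment, threshold 0.05), for each age alone. A miRNA was tested when it had at least 1 RPM in at least as many libraries as the smaller group holds, 4 at 14 weeks and 3 at 9 weeks. Fold changes are on the log2(RPM + 0.5) scale, which understates changes of rare miRNAs. The difference of the ob/ob effect between the ages was the interaction of genotype and age in a model of all 15 libraries. Contrasts of 14 against 9 weeks within a genotype were planned for count data and were not run. Two-sided exact permutation tests were used for single library measures. The smaller tail was doubled for sums and depths, and absolute differences of means were counted for GC slopes and log2 ratios. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

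Because the sums of the listed miRNAs differed between libraries, each comparison was repeated after median-ratio rescaling, a choice made after seeing the data. Each library was divided by the median ratio of its miRNAs to their geometric mean over the libraries of that age, over miRNAs with no 0 and a mean of at least 5 RPM. A further fit added a linear GC correction per library, with the GC percentage of the side of the hairpin that holds the mature arm, available for 244 of the 248 miRNAs from GENCODE vM21 (GRCm38). Positions are from the same annotation, 1-based.

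The 15 lists of miRNAs (cell type markers, inflammation, regulators reported for Nfe2l2 and Keap1, lipid metabolism, families and clusters) were fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists. Named miRNAs were, per comparison, the 10 largest rises and the 10 largest falls among those past the threshold with a mean of at least 10 RPM in the higher group, up to 4 members per list by smallest p, and a fixed group. Of that group miR-144-3p, miR-451a and miR-223-3p were not analysed here, and miR-144-5p, also in the group, was measured. For the interaction the 5 smallest p in each direction were named, and the 5 most abundant miRNAs are given as description.

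On simulated data with 40 changed miRNAs in each of 20 runs, the test recovered 67.4% of 2-fold and 94.4% of 4-fold changes at 9 weeks (168 miRNAs) and 67.2% and 96.4% at 14 weeks (162 miRNAs). The interaction recovered 43.2% and 87.4% (175 miRNAs). The share of false calls lay between 3.31% and 6.10%. The simulated values were drawn from the rescaled libraries, without miRNAs that switch on and off within a group. Noise was normal and independent between miRNAs, and rises and falls were equal in number. These rates therefore do not cover the as-deposited values, with their shifted medians, exact zeros and related miRNAs.

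Alternatives set before the data were examined were no filter, a mean of at least 10 RPM, a pseudocount 10 times larger, the miR-144 and miR-122 arms taken out of the denominator, each library left out in turn, a replicate block, lane as a covariate, each lane alone, the lane shared by both ages and a joint fit of both ages. Alternatives added after seeing the data were the rescalings, zeros as missing, the GC correction, leaving out miRNAs that switch on and off within a group, rescaling with a replicate block or with lane, fry after rescaling, and rescaling without the first wt replicate of 14 weeks. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9.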

Results

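Small RNA profiles of Kupffer cells from lean wt and obese ob/ob mice were compared at 9 and 14 weeks of age. The series concerns the antioxidant response in obesity-associated insulin resistance, and the comparisons ask which miRNAs of these macrophages differ with obesity at each age. The 248 listed miRNAs summed to 336291 ± 28950 RPM (reads per 1000000 reads, SD, n = 4) in wt and 242718 ± 10479 (n = 3) in ob/ob at 9 weeks (two-sided exact permutation p = 0.0571). At 14 weeks they summed to 287749 ± 94754 (n = 4) in wt and 313352 ± 27489 (n = 4) in ob/ob (exact permutation p = 0.829). The first wt replicate of 14 weeks stood apart with a sum of 147387. The depth implied by the worth of 1 read, in units of 1000000 reads (M), was 16.1 ± 4.44 M in wt and 31.0 ± 4.46 M reads in ob/ob at 9 weeks (exact permutation p = 0.0571), and 24.0 ± 12.2 and 63.2 ± 24.0 M reads at 14 weeks (exact permutation p = 0.0286). At 9 weeks neither sums nor depths overlapped between the genotypes. There 0.0571 is the smallest p this test can give for 4 against 3 libraries. Log2 values of replicates correlated across miRNAs with Pearson's r of 0.952 to 0.988, although miRNAs are not independent replicates.

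**Figure D1:**
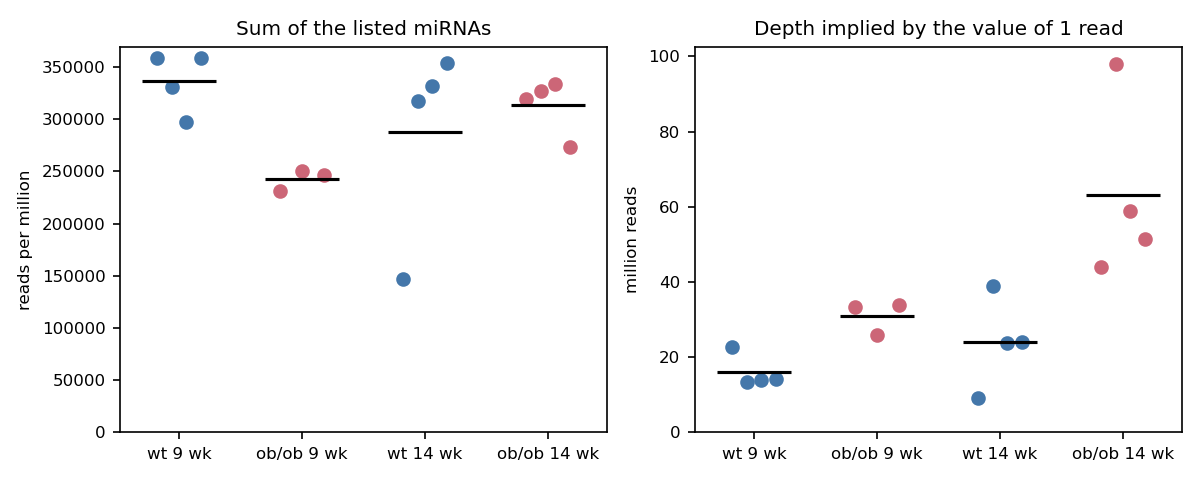
Sum of the 248 listed miRNAs in RPM (left) and implied depth in reads (right) for each library, with points for libraries and lines for group means. The first wt replicate of 14 weeks has a sum of 147387 RPM, and the ob/ob libraries of 14 weeks have the highest mean depth, 63.2 M reads.

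The most abundant miRNAs were miR-22-3p, miR-126a-5p, miR-21a-5p, miR-10a-5p and let-7f-5p. miR-126a-5p comes from an intragenic hairpin in the endothelial gene Egfl7 and is known from endothelial cells. It was at 46882 ± 8258 RPM in wt and 31868 ± 13512 in ob/ob at 9 weeks, and at 42482 ± 22150 and 45363 ± 9109 at 14 weeks, and did not pass the test at either age. Its partner arm miR-126a-3p was listed at 0 in ob/ob replicate 2 of 14 weeks and at 1538 RPM or more in the other 3 ob/ob libraries.

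At 9 weeks, libraries from ob/ob Kupffer cells held more miR-144-5p, miR-146b-5p, miR-192-5p, miR-184-3p, miR-122-5p and miR-34a-5p. They held less miR-423-5p, miR-1964-3p, miR-188-5p, let-7d-3p and miR-125a-5p. Whether these miRNAs came from the Kupffer cells or from other cells in the preparation is not settled by these values. miR-144-5p, from the erythroid miR-144 hairpin cluster on chromosome 11 (Mir144, 78073005 to 78073070, plus strand), rose from 1.03 ± 0.44 RPM (n = 4) to 17.6 ± 3.66 (n = 3), a log2 fold change of 3.59 ± 0.29 (SE, limma adjusted p = 0.000266). miR-192-5p, abundant in hepatocytes (Mir192, chromosome 19, 6264844 to 6264932), rose from 1556 ± 459 to 4494 ± 743 RPM (log2 fold change 1.57 ± 0.27, adjusted p = 0.00529). miR-146b-5p, of the inflammation-induced list, rose from 94.1 ± 58.2 to 645.3 ± 342.8 RPM (adjusted p = 0.00917). miR-423-5p, from an intron of Nsrp1 (chromosome 11, 77078064 to 77078172, minus strand), fell from 796.5 ± 116.1 to 192.9 ± 80.5 RPM (log2 fold change -2.11 ± 0.28, adjusted p = 0.00350).

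Of 179 miRNAs tested at 9 weeks, 67 differed as deposited, 9 higher and 58 lower in ob/ob, around a median log2 fold change of -0.51. After median-ratio rescaling, which sets the median near 0, 38 of 177 differed, 20 higher and 18 lower, and 27 were called on both scales, 9 higher and 18 lower. The named miRNAs above were called on both scales. The call for miR-122-5p, the main hepatocyte miRNA (46.3 ± 29.0 and 166.2 ± 57.9 RPM, adjusted p = 0.0244), was lost without ob/ob replicate 2 (adjusted p = 0.0717) or replicate 3 (adjusted p = 0.0964). miR-151-5p and miR-674-3p fell as deposited, with adjusted p of 0.112 and 0.0534 after rescaling. Calls also ended without wt replicate 1 or 2 for miR-151-5p (adjusted p up to 0.0629) and without wt replicate 2 or 3 or ob/ob replicate 1 or 2 for miR-31-5p (up to 0.0655).

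By list at 9 weeks, 6 of the 9 tested let-7 family members were lower and none higher, let-7f-5p falling from 33927 ± 4279 to 16079 ± 3099 RPM (adjusted p = 0.00501). After rescaling 3 were lower and 1 higher, and with the GC correction 2 were lower and 1 higher. All 3 tested members of the cluster of miR-99b, let-7e and miR-125a on chromosome 17 were lower on both scales, miR-125a-5p falling from 1977 ± 570 to 622.0 ± 219.4 RPM. With the GC correction 2 were, and the call of let-7e-5p ended (log2 fold change -0.69 ± 0.21 rescaled and -0.58 ± 0.22 corrected, adjusted p = 0.0469 and 0.102). Of 4 tested hepatocyte miRNAs 2 rose, miR-122-5p and miR-192-5p, and miR-194-5p was called after rescaling only (adjusted p = 0.195 as deposited and 0.0238 rescaled). This was the only list called by camera (adjusted p = 0.00451, and adjusted p = 0.417 with an estimated correlation). Of 8 inflammation-induced members miR-146b-5p rose and miR-132-3p fell, the latter not after rescaling (adjusted p = 0.201). miR-146a-5p, at 1583 ± 983 RPM in wt and 3746 ± 1361 in ob/ob, passed after rescaling only (adjusted p = 0.0882 as deposited and 0.0435 rescaled). Among lipid and obesity miRNAs, 1 of 10 rose, miR-34a-5p from 5.54 ± 1.72 to 13.6 ± 1.51 RPM, and 3 fell as deposited, miR-29c-3p, miR-103-3p and miR-29a-3p, with adjusted p of 0.0809, 0.0852 and 0.609 after rescaling and 0.0477, 0.0646 and 0.203 with the GC correction. The call of miR-132-3p ended without wt replicate 1 or 2 or ob/ob replicate 1 or 3 (adjusted p up to 0.0763), and that of miR-29a-3p without any library but ob/ob replicate 2 (up to 0.0995).

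miR-199a-3p, of stellate and mesenchymal cells, fell from 901.7 ± 126.2 to 316.6 ± 99.9 RPM (adjusted p = 0.00525 and 0.0371 rescaled), and 3 of 6 members of that list were lower as deposited and 1 after rescaling. The calls of miR-214-5p and miR-214-3p ended after rescaling (adjusted p = 0.141 and 0.310). As deposited they also ended without wt replicate 2 or 4 for miR-214-5p (up to 0.0535) and without wt replicate 1, 2 or 4 or ob/ob replicate 2 or 3 for miR-214-3p (up to 0.0967). Of the 2 endothelial arms, miR-126a-3p was lower as deposited (adjusted p = 0.0230) but not after rescaling (adjusted p = 0.273). None of 3 lymphocyte and none of 4 biliary members passed as deposited, and miR-141-3p of the biliary list did after rescaling (log2 fold change 0.91 ± 0.26, adjusted p = 0.0435) but not with the GC correction (0.82 ± 0.27, adjusted p = 0.0585). miR-511-3p, from an intron of the macrophage mannose receptor gene, was at 159.0 ± 11.8 RPM in wt and 77.9 ± 23.9 in ob/ob (adjusted p = 0.00984 as deposited and 0.0860 rescaled). Of the miRNAs reported to target Nfe2l2, miR-142a-5p and miR-93-5p were tested and neither passed. Of those reported to target Keap1, miR-200a-3p did not pass and miR-141-3p passed after rescaling only. In the miR-17-92 cluster and its paralogues 1 of 4 was lower, miR-92a-3p, which did not pass after rescaling, where miR-19a-3p was higher (12.6 ± 3.22 and 17.3 ± 1.74 RPM, adjusted p = 0.147 as deposited and 0.0208 rescaled), and none of 7 Dlk1-Dio3 members passed. miR-20a-5p of the miR-17-92 cluster was listed at 0 in wt replicates 2 and 3 and ob/ob replicate 2, and at 27.8 to 43.4 RPM in the other 4 libraries. The calls of miR-126a-3p ended without wt replicate 2 (adjusted p = 0.0639) or 4 (0.0529), and of miR-92a-3p without wt replicate 1 or 2 or ob/ob replicate 3 (up to 0.0595). Adjusted over the list alone, 6 let-7, 4 lipid, 3 stellate, 3 miR-99b cluster, 2 hepatocyte, 2 inflammation-induced, 2 myeloid, 1 endothelial and 1 miR-17-92 member passed as deposited.

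At 14 weeks, libraries from ob/ob Kupffer cells again held more miR-144-5p, miR-192-5p, miR-34a-5p and miR-146b-5p, with miR-19a-3p, miR-210-3p and miR-374b-5p. They held less miR-423-5p, miR-1964-3p, miR-674-3p and let-7d-3p. miR-144-5p rose from 0.77 ± 0.29 (n = 4) to 21.4 ± 8.73 RPM (n = 4), a log2 fold change of 4.06 ± 0.35 (limma adjusted p = 0.000108). miR-192-5p rose from 1317 ± 247 to 5212 ± 1590 RPM (log2 fold change 1.94 ± 0.30, adjusted p = 0.00256). miR-19a-3p of the miR-17-92 cluster (chromosome 14, 115044000 to 115044081) rose from 10.6 ± 3.17 to 62.3 ± 26.8 RPM (log2 fold change 2.45 ± 0.37, adjusted p = 0.00256). miR-210-3p, a hypoxia-induced miRNA, rose from 2.34 ± 0.68 to 10.9 ± 3.08 RPM (adjusted p = 0.00256), and miR-34a-5p, a target of p53, from 4.76 ± 1.17 to 18 ± 4.56. miR-423-5p fell from 546.9 ± 58.6 to 147.0 ± 89.1 RPM (log2 fold change -2.06 ± 0.38, adjusted p = 0.00631).

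Of 171 miRNAs tested at 14 weeks, 26 differed as deposited, 20 higher and 6 lower, around a median of 0.20. After rescaling 48 of 168 differed, 26 higher and 22 lower, and 24 were called on both scales, 18 higher and 6 lower. Without the low first wt replicate, 46 were called as deposited, 25 higher and 21 lower, and 48 after rescaling. The count fell to 15 without wt replicate 3 and to 13 without ob/ob replicate 3. Within lanes, 2 libraries against 2, lane 1 alone gave 1 call and lane 2 alone 51. The single call in lane 1 was among the 26. Calls of miR-146b-5p and let-7d-3p were lost by the narrowest margin without ob/ob replicate 3 (adjusted p = 0.05005 for each), and that of miR-146b-5p also without wt replicate 3 (adjusted p = 0.0629).

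By list at 14 weeks, none of 9 let-7 members passed as deposited and 6 were lower after rescaling and 5 with the GC correction, let-7a-5p at 6563 ± 1883 RPM in wt and 4518 ± 784 in ob/ob (adjusted p = 0.264 as deposited and 0.0102 rescaled). In the miR-99b, let-7e and miR-125a cluster 1 of 3 was lower as deposited, 3 after rescaling and 2 with the GC correction, which ended the call of let-7e-5p (log2 fold change -0.92 ± 0.29 rescaled and -0.66 ± 0.25 corrected, adjusted p = 0.0449 and 0.0829). Of 4 hepatocyte miRNAs 2 rose, miR-192-5p and miR-194-5p, the latter not after rescaling (adjusted p = 0.120), where miR-215-5p, at 43.3 ± 19.6 and 96.3 ± 39.9 RPM, passed instead (adjusted p = 0.117 as deposited and 0.0457 rescaled), though not with the GC correction (log2 fold change 1.0 ± 0.32 rescaled and 0.92 ± 0.31 corrected, adjusted p = 0.0608). miR-122-5p was at 46.7 ± 39.2 RPM in wt and 54.9 ± 17.9 in ob/ob (adjusted p = 0.551). Of 8 inflammation-induced members miR-146b-5p and miR-155-5p rose, miR-155-5p from 7.54 ± 3.11 to 18.9 ± 4.40 RPM (adjusted p = 0.0201). The call of miR-155-5p was lost without wt replicate 3 (adjusted p = 0.0580), wt replicate 4 (0.0620), ob/ob replicate 2 (0.0780) or, by the narrowest margin, ob/ob replicate 3 (0.05005), and with the GC correction (log2 fold change 1.10 ± 0.28 rescaled and 0.82 ± 0.30 corrected, adjusted p = 0.0751). Of 10 lipid and obesity miRNAs 2 rose, miR-34a-5p and miR-335-3p, and after rescaling 4 did, with miR-29b-3p (30.4 ± 8.58 and 61.3 ± 14.3 RPM, adjusted p = 0.0535 as deposited and 0.0322 rescaled) and miR-335-5p (73.4 ± 40.1 and 190.5 ± 64.8 RPM, adjusted p = 0.0930 and 0.0324). The GC correction ended both added calls, with log2 fold changes of 0.80 ± 0.23 rescaled and 0.40 ± 0.22 corrected for miR-29b-3p (adjusted p = 0.232) and of 1.41 ± 0.41 and 1.14 ± 0.40 for miR-335-5p (adjusted p = 0.0691). Leaving out any library but the first replicate of either genotype ended the calls of let-7e-3p, the member of the chromosome 17 cluster that fell (adjusted p up to 0.102), and of miR-194-5p (up to 0.128). That of miR-335-3p ended without wt replicate 3 or 4 or ob/ob replicate 1, 2 or 3 (up to 0.111).

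No list was called by camera at 14 weeks. The smallest adjusted p was 0.0856, for the miR-99b cluster, and that of the hepatocyte list was 0.144, against 0.744 and 0.666 with an estimated correlation. fry, which tests whether members move one way on balance, called 3 lists at 14 weeks, hepatocyte, inflammation-induced and miR-17-92, and 5 at 9 weeks, hepatocyte upwards and lymphocyte, lipid, let-7 and the miR-99b cluster downwards. By camera with an estimated correlation none of these passed, with adjusted p = 0.666, 0.744 and 0.744 at 14 weeks and 0.417, 0.762, 0.987, 0.687 and 0.687 at 9 weeks, in the same order. After rescaling fry called 2 lists at 9 weeks, hepatocyte upwards and the miR-99b cluster downwards (adjusted p = 0.629 for each by camera with an estimated correlation). There let-7 no longer passed (adjusted p = 0.0693), and lymphocyte and lipid turned upwards without passing (adjusted p = 0.607 for each). At 14 weeks it then called 6, with hepatocyte, biliary, lipid and miR-17-92 upwards and let-7 and the miR-99b cluster downwards, and no longer the inflammation-induced list (adjusted p = 0.141). By camera with an estimated correlation, adjusted p of the 6 was 0.598 for miR-17-92 and 0.579 for each of the others. Median, mean and test differed in sign for some uncalled lists, as for the stellate list at 9 weeks (median -0.89, mean -0.41, camera upwards) and at 14 weeks (median -0.06, mean 0.96), the inflammation-induced list at 9 weeks (median -0.04, mean 0.34) and the Dlk1-Dio3 list at 9 weeks (median 0.09, mean -0.12). The stellate means include miR-199b-3p, listed at 0 in wt replicate 3 of 9 weeks beside 73.7 to 203.2 RPM in the other libraries (log2 fold change 1.68 ± 2.22), and at 0 in wt replicates 1 and 4 of 14 weeks beside 60.8 to 336.8 RPM (5.25 ± 2.02, adjusted p = 0.120). Neither endothelial arm, none of 6 stellate, none of 3 lymphocyte, neither of 2 myeloid and none of 5 Dlk1-Dio3 members passed as deposited. After rescaling miR-143-3p of the stellate list did, at 462.2 ± 212.2 RPM in wt and 1104 ± 480 in ob/ob (adjusted p = 0.0749 as deposited and 0.0488 rescaled), and with the GC correction it did not (log2 fold change 1.05 ± 0.34 rescaled and 1.15 ± 0.38 corrected, adjusted p = 0.0566). With that correction, though neither as deposited nor rescaled without it, the lymphocyte miR-150-5p (170.1 ± 72.1 and 261.4 ± 29.1 RPM, adjusted p = 0.0472), the myeloid miR-511-3p (150.5 ± 49.6 and 129.8 ± 20.3 RPM, adjusted p = 0.0166) and the lipid list's miR-103-3p (98.1 ± 19.0 and 76.1 ± 11.5 RPM, adjusted p = 0.0381) passed. miR-141-3p, in the biliary and Keap1 lists, was at 23.5 ± 6.23 and 56.2 ± 19.0 RPM (adjusted p = 0.0495), just under the threshold, and leaving out any library but ob/ob replicate 1 ended that call, with adjusted p between 0.0562 and 0.142, as did the GC correction (log2 fold change 0.99 ± 0.31 rescaled and 0.88 ± 0.33 corrected, adjusted p = 0.0829). Neither miR-142a-5p nor miR-93-5p, reported to target Nfe2l2, passed. miR-93-5p, also 1 of the 3 tested members of miR-17-92 and its paralogues, was listed at 0 in wt replicate 2 (log2 fold change 3.03 ± 2.20). The other wt libraries had 233.9 to 383.9 RPM and the ob/ob libraries 470.5 to 557.8. In the same list miR-92a-3p did not rise (log2 fold change -0.16 ± 0.23, adjusted p = 0.693, and -0.38 ± 0.20 rescaled). Of its tested members only miR-19a-3p was called, on either scale. miR-20a-5p was listed at 0 in 6 of the 8 libraries and was not tested. Adjusted over the list alone, 3 hepatocyte, 3 inflammation-induced, 3 lipid, 2 miR-99b cluster, 1 miR-17-92, 1 biliary and 1 Keap1 member passed as deposited. The erythroid list held miR-144-5p alone.

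**Figure D2:**
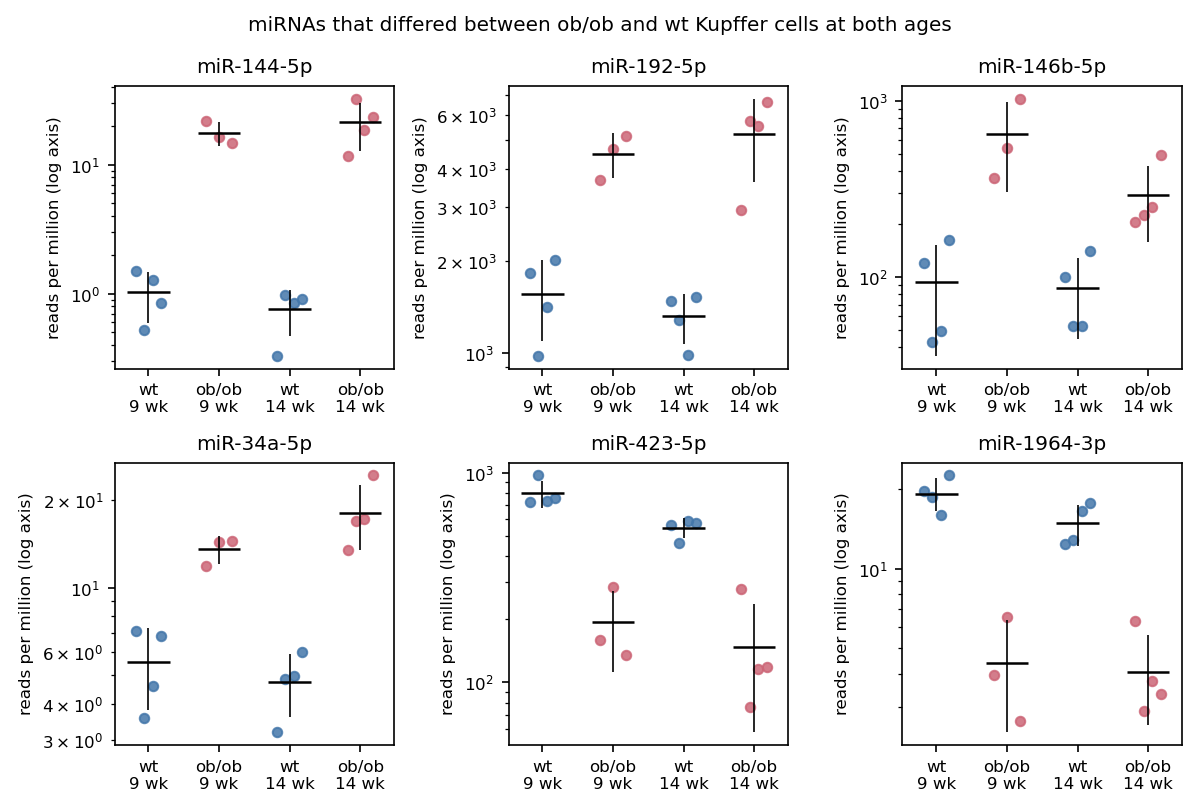
RPM on a log axis for 6 miRNAs in each group, with points for libraries, horizontal lines for group means and vertical lines for 1 SD. miR-144-5p, miR-192-5p, miR-146b-5p and miR-34a-5p lie higher in ob/ob and miR-423-5p and miR-1964-3p lower at both ages, with miR-144-5p at 0.77 RPM in wt and 21.4 in ob/ob at 14 weeks.

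Called at both ages and on both scales were 11 miRNAs, 7 higher and 4 lower in ob/ob. The 7 were miR-144-5p, miR-146b-5p, miR-192-5p, miR-210-3p, miR-31-5p, miR-34a-5p and miR-582-3p, and the 4 were let-7d-3p, let-7e-3p, miR-1964-3p and miR-423-5p. miR-582-3p was named after its values were seen. With the GC correction 10 of the 11 were called at both ages, and miR-146b-5p was not at 14 weeks (log2 fold change 1.57 ± 0.51 rescaled and 1.54 ± 0.52 corrected, adjusted p = 0.0608). After rescaling, 12 miRNAs were higher at both ages, where independent lists of 20 and 26 among 165 would share 3.15 (one-sided Fisher's exact p = 1.05e-06), and 12 were lower at both, with 2.40 for independent lists (p = 1.46e-08). These p-values treat miRNAs as independent, which arms of a hairpin, clusters and families are not. The ages had separate control libraries, but the ob/ob libraries were deeper at both ages. A technical shift common to both ages is thus not excluded as a source of the overlap. Across 165 miRNAs the rescaled log2 fold changes of both ages correlated with Pearson's r of 0.72, although miRNAs are not independent replicates.

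**Figure D3:**
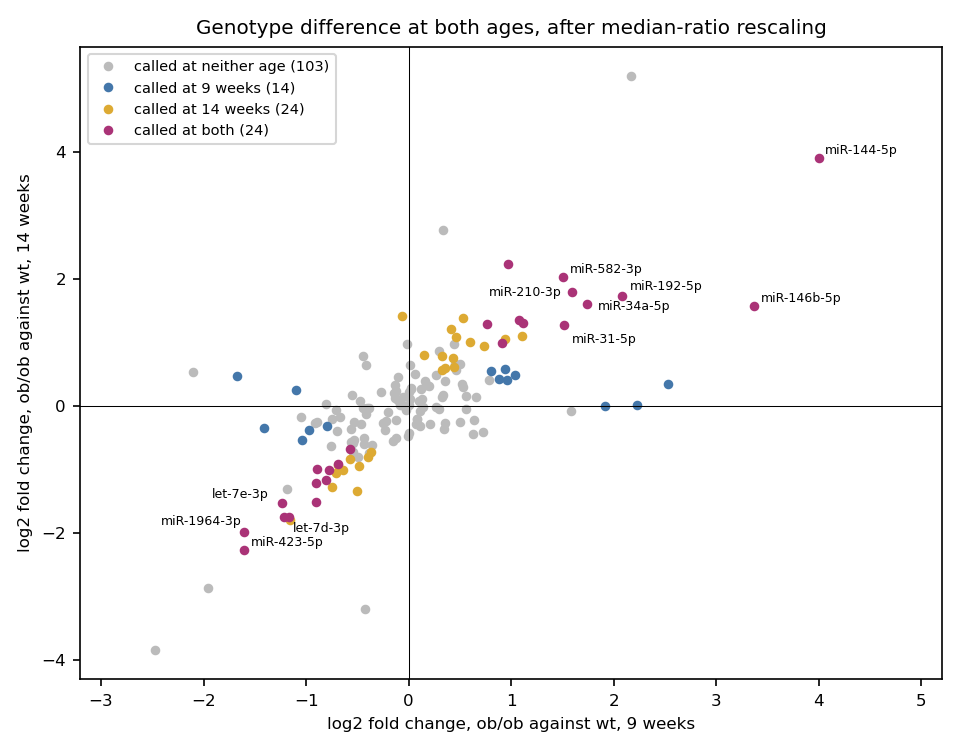
Log2 fold change of ob/ob against wt after median-ratio rescaling at 9 weeks (x axis) and 14 weeks (y axis), 1 point per miRNA, with colours for the age at which it was called. Called at both ages were 24 miRNAs, at 9 weeks only 14 and at 14 weeks only 24, and names mark the 11 also called as deposited at both ages.

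The difference of the ob/ob effect between the ages was tested in all 15 libraries. None of 187 miRNAs passed with limma as deposited, where 48 had an unadjusted p under 0.05 around a median difference of 0.68, and none passed after rescaling, where 16 did. The smallest p was that of miR-188-5p, whose log2 fold change was -2.14 at 9 weeks and 0.66 at 14 weeks (difference 2.80 ± 0.64, adjusted p = 0.0510). The differences of miR-138-5p and miR-19a-3p were 1.96 and 1.97 (adjusted p = 0.0510 for each), and those of miR-34c-5p and miR-29b-3p 1.38 and 1.37 (adjusted p = 0.0948 and 0.132). After rescaling the difference of miR-188-5p was 2.14 (adjusted p = 0.111), those of miR-138-5p and miR-19a-3p 1.35 and 1.27 (adjusted p = 0.266 for each), and those of miR-34c-5p and miR-29b-3p 0.79 and 0.65 (adjusted p = 0.351 and 0.568). In the other direction were miR-184-3p (difference -1.50, adjusted p = 0.132, and -2.22 with adjusted p = 0.266 rescaled), miR-146a-5p and miR-122-5p (adjusted p = 0.271 for each) and miR-146b-5p (adjusted p = 0.354). miR-151-3p (difference -5.67 ± 3.79) was at 827.4 RPM in ob/ob replicate 3 of 9 weeks and 1401 in wt replicate 4 of 14 weeks, and at 0 to 4.40 in all other libraries. All 9-week libraries were in lane 2, and with that lane alone 2 miRNAs passed.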

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

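Of the tests in this part, the splits of the libraries as deposited were set before their results were seen, and those of miR-144-5p, miR-192-5p, the rescaled calls, the interaction and the GC trend after. Other splits of the 7 libraries of 9 weeks gave at most 2 calls against the real 67, and 2 against 38 after rescaling, and in each case 1 of 35 splits, the real one, reached the real count. At 14 weeks no other split gave a call against the real 26 as deposited or 48 rescaled (highest 0), again 1 of 35. A share of 1 of 35 is the smallest these splits can give, so chance is made unlikely for these counts but not excluded. The splits also cannot separate genotype from depth or GC slope, which follow it. For the interaction this comparison decides nothing, since with 0 real calls all 100 label orders reach that count by construction (highest 2).

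miR-144-5p was higher in ob/ob at both ages. After the linear GC correction its log2 fold change was 3.79 at 9 weeks and 3.59 at 14 weeks. This decides nothing about GC bias as a cause, since the fitted slopes were too small to remove a change of this size. Other forms of GC or sequence bias were not tested. Within groups it rose with sequencing depth (Pearson's r = 0.743, permutation p = 0.0022). By that relation the depth gap between genotypes predicts 19.2% of the rise, and 31.4% at the upper 95% bound. Depth did not overlap between the genotypes at either age, so this is an extrapolation. It argues against depth as the whole cause only if the relation holds across the gap. Red blood cell RNA cannot be told apart from a change in the Kupffer cells, since 0 other members of the erythroid list were measured. A difference that goes with genotype stays open as a hypothesis.

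miR-192-5p was higher at both ages, and its GC-corrected log2 fold change stayed at 1.69 or more. Hepatocyte RNA would bring miR-122-5p, the most abundant hepatocyte miRNA, yet the rise of miR-122-5p in RPM was 4.08% of that of miR-192-5p at 9 weeks and 0.21% at 14 weeks, at most 10.7% and 2.81% with the extreme libraries. This comparison decides nothing about hepatocyte RNA as the source. It assumes that the tables count both miRNAs alike. miR-122-5p was also far below miR-192-5p in every group, levels that had already been seen. The log2 ratio of miR-192-5p to miR-122-5p changed by -0.46 at 9 weeks (exact permutation p = 0.343) and by 1.38 at 14 weeks (exact permutation p = 0.0857). At 9 weeks the log2 fold changes were 1.57 for miR-192-5p and 2.02 for miR-122-5p, so a common source is not excluded there. The comparison in RPM replaced that of the ratio after the latter had been seen. Neither settles the source of miR-192-5p or of miR-122-5p.

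The GC slope of the libraries separated the genotypes at both ages. After rescaling it was 0.065 ± 0.053 log2 per 10 percentage points of GC in wt and -0.086 ± 0.0070 in ob/ob at 9 weeks (exact permutation p = 0.0571). At 14 weeks it was 0.133 ± 0.026 and -0.133 ± 0.096 (exact permutation p = 0.0286). Each slope was fitted to deviations from the mean of each miRNA over all libraries of that age. The opposite signs of the genotypes are therefore built in, and only the gap between them carries information. That gap restates how the fold changes between genotypes trend with GC. As the whole cause of the rescaled calls a linear GC trend is argued against, since 78.9% of them at 9 weeks and 75.0% at 14 weeks kept their call after its removal. Other forms of GC or sequence bias were not tested. Within groups the slope showed no clear relation to depth (Pearson's r = -0.214, permutation p = 0.4735). By that relation depth predicts 13.2% of the gap in slope, with an upper bound of 55.6%. Depth and genotype thus cannot be told apart as its source.

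Single libraries far from the other 3 of their group were found in 11 of 172 groups tested, where chance gives about 8.6. In the first wt replicate of 14 weeks miR-126a-3p (747.4 RPM), miR-199a-3p (259.9), miR-21a-5p (13315) and miR-10a-5p (13356) were low as deposited. That library was low as a whole, with a sum of 147387 RPM and a rescaling factor of 0.578 against 1.11 to 1.15 in the other wt libraries. Its flags are thus not independent of each other. In the same age miR-142a-3p was 0.084 RPM in wt replicate 3 with the others at 0, and 0.16 in ob/ob replicate 1 with the others at 17.1 to 18.6, miR-146b-5p was 495.0 in ob/ob replicate 4, and miR-141-3p 27.9 in ob/ob replicate 1. At 9 weeks miR-423-5p was 969.3 in wt replicate 2, miR-155-5p 15.6 in wt replicate 3, and miR-142a-3p was listed at 0 in wt replicate 3.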

How the results depend on the processing

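Rescaling, GC correction, zeros as missing, fry after rescaling and leaving out switching miRNAs were chosen after seeing the data. The cause of a change was not tested unless named. At 14 weeks the 26 calls became 17 with a mean of 10 RPM or more (fewer miRNAs tested), 1 in lane 1 alone and 51 in lane 2 alone (2 against 2), 48 in the joint fit, 48 after either rescaling, 40 with the GC correction, 44 rescaled with lane, and 48 rescaled without the first wt replicate. Leaving out 1 library gave 13 to 46. At 9 weeks the 67 calls became 38 after median-ratio rescaling, 35 after rescaling to the listed total and 34 with the GC correction, and 53 to 71 with 1 library left out. The interaction gave 4 without a filter, 2 with a mean of 10 RPM or more, 2 in the shared lane, 3 with zeros as missing, 3 without the switching miRNAs, and 0 to 3 with 1 library left out (3 without wt replicate 2, 1 without wt replicate 3 and 2 without ob/ob replicate 1 of 14 weeks). Lists called at 9 weeks went from 1 to 0 with an estimated correlation and to 5 with fry (2 with fry after rescaling), and at 14 weeks from 0 to 3 with fry (6 with fry after rescaling), and stayed at 1 and 0 with each library left out. Count-based alternatives and the age contrasts were not run, since whole reads were not recovered.

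miR-144-5p kept its direction and call in all 25 alternatives at 14 weeks (log2 fold change 2.14 to 4.31) and all 18 at 9 weeks (1.90 to 4), with the lowest values at the larger pseudocount. Of the other named miRNAs, 21 of 30 called at 9 weeks and 8 of 18 called at 14 weeks kept their call with each library left out. No call reversed. Rare miRNAs rest on few reads in the shallowest library, where 1 RPM is 9.08 reads.

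The replicate numbers gave no clear sign of pairing. Same-numbered deviations correlated at 0.28, 0.14 and -0.14 at 9 weeks and at -0.23, 0.10, 0.18 and 0.096 at 14 weeks, and not every sample correlated best with its own number. At 9 weeks a library number is skipped within ob/ob. Matched by library order, wt replicates 1, 3 and 4 correlated with ob/ob replicates 1, 2 and 3 at 0.28, 0.34 and 0.11. Pairing in that order is thus not excluded. With the block by replicate number, which leaves fewer residual degrees of freedom, 32 miRNAs were called at 9 weeks, 13 with rescaling, 22 at 14 weeks, 36 with rescaling, and 2 in the interaction.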

Other observations

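Outside the comparisons, miR-205-5p, an epithelial miRNA, was listed at 0 in all 4 wt libraries of 14 weeks and at 0.38 to 0.82 RPM in the 4 ob/ob libraries. At 9 weeks it was at 0.50 to 0.77 RPM in ob/ob, at 0 in 3 wt libraries and at 0.57 in the other. miR-375-3p, an endocrine and epithelial miRNA, was listed at 0 in all 4 ob/ob libraries of 14 weeks and at 0.42 to 1.43 RPM in wt, whereas at 9 weeks its ob/ob values of 0.39 to 1.06 overlapped those of wt, 0 to 0.67. Both lay below the filter, were not tested, and were chosen after their values were seen. miR-142a-3p, a leukocyte miRNA, was listed at 0 or below 0.16 RPM in all libraries but ob/ob replicates 2, 3 and 4 of 14 weeks, which had 17.1 to 18.6, while the other arm of its hairpin, miR-142a-5p, was at 2415 ± 449 RPM in wt and 3279 ± 722 in ob/ob at that age.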
